A study of Mus musculus with 2 samples.

How the data were processed

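RNA from 2 pools of RAW264.7 clones, 1 infected with empty MSCV vector and 1 with MSCV encoding miR-155, was measured on 1 Affymetrix array each. Per the labels' protocols, cells were selected with puromycin at 7 µg/ml, single clones were obtained by limiting dilution, RNA from 5 clones was pooled per arm, and biotin-labelled material was processed by the manufacturer's procedures. The deposited values are probeset intensities on a linear scale. The summarisation software, background correction, scaling and detection calls are not given in the sources used here. From the values, all 45101 intensities per array are positive, and the median (15.4 and 14.1) and the mean with 2% trimmed at each end (108.8 and 104.7, empty vector first) differ between the arrays, so a common trimmed mean of all probesets was not their last step. Without detection calls, the precision of dim probesets is known only from the spread of ratios at like signal, and the number of arrays limits every statement.

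Probesets were named through the platform annotation, with symbols updated by Entrez identifier through the RefSeq gene table of assembly GRCm38.p6. No symbol changed, and 34741 probesets had an identifier in that table. Leaving out 64 control probesets, 34945 probesets had 1 gene symbol, 932 had several and 9160 were unlisted; genes were named only from probesets with 1 symbol. The decision to leave out the control probesets was taken after the data were seen. The genome build of the array design is not given in the sources used here, so no coordinates are printed and the table was used only for names and for the order of neighbouring genes. Among 9 hybridisation spike-in control probesets the median log2 ratio was 0.057 (range −0.077 to 0.13), and among the 9 further ones for the same transcripts 0.095 (−0.093 to 0.23). The signal ratio of the 3′ to the 5′ control probesets was 1.30 and 1.26 for Actb and 0.79 and 0.81 for Gapdh (empty vector first). Log2 signals correlated across probesets with r = 0.90, and across the genes kept with r = 0.97; probesets and genes are not independent replicates.

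The log2 ratio was log2 of the miR-155 signal minus log2 of the empty-vector signal, as deposited, with no offset. Each of 18193 genes was represented by its probeset with the highest mean log2 signal, and the 9097 genes in the upper 50% of that mean (geometric mean signal of at least 25.8) were kept. Their median log2 ratio was −0.048. The filter acts on the mean, so 332 of them had a reading below 25.8 on 1 array; no ratio of these is printed for single genes, a choice made after the data were seen. With 1 array per group there was no residual degree of freedom, and no test, standard error or p-value was computed. Genes were counted at 2-fold, with 1.5-fold and 4-fold beside it. As measures of spread, the SD of the ratio was estimated from the scaled median absolute deviation among the 500 genes nearest in signal. The same estimate from the differences between probesets of one gene was 0.22, over 4115 genes with 6576 further probesets. Of the genes at least 2-fold higher, 42 had a further probeset. The median of the further probesets had the same direction in 38 and was at least 1.5-fold that way in 26. Of those at least 2-fold lower, 34 had one, with the same direction in 32 and at least 1.5-fold that way in 27.

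There were 31 gene lists, written with the comparisons, the alternatives and the rule for named genes before the data were examined. A list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins; this describes the 2 arrays, and because genes of a pathway are regulated together while random lists are not, a percentile is not a p-value. The lists were reported miR-155 targets, myeloid follow-up genes of miR-155, interferon-stimulated genes, inflammatory NF-κB genes, chemokines and receptors, macrophage, osteoclast, MHC class I, MHC class II, lysosome, cholesterol synthesis, lipid efflux and storage, glycolysis and hypoxia, heme and NRF2, stress responses, immediate-early, DNA replication, mitosis, p53 and apoptosis, ribosomal protein, mitochondrial respiration, housekeeping, microRNA processing, cytoskeleton and adhesion and cytokine signalling genes, and markers of B, T and NK, neutrophil and mast, dendritic, stromal and erythroid cells. Lists overlap: all 9 measured follow-up genes are among the targets, 3 macrophage genes (Csf1r, Spi1, Cebpb) are too, and 3 genes (Fos, Fosl1, Fosl2) are both immediate-early and osteoclast genes. Named were the 15 highest and 15 lowest genes kept, every follow-up gene on the array, the 8 lowest and 3 highest reported targets, and the 4 largest ratios of each other list that lay outside its random range or had at least 3 members beyond 1.5-fold in 1 direction.

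The steps were tested on simulated ratios for the 9097 genes, drawn from a normal distribution with the spread observed between the compared arrays. At the 2-fold threshold, 1 of 50 genes with a true 1.5-fold difference, 21 of 50 with 2-fold and 50 of 50 with 4-fold were recovered, and 133 of 8897 unchanged genes passed. Of 200 unshifted lists of 30 genes 7 fell outside the 95% range, and 200 of 200 lists shifted by −0.3 fell below it. Alternatives were another scaling (median log2 ratio set to 0, quantile normalisation, or loess with a span of 0.3), no filter or the upper 25% of signal, an offset of 50, the mean of all probesets of a gene, and probesets without a suffix for shared or alternative transcripts (plain probesets). The analysis of miR-155 seed sites in 3′ untranslated regions that had been planned was not run, because transcript sequences were not used here. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.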

Results

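Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, after infection with the retroviral vector MSCV, either empty or encoding the microRNA miR-155. Infected cells had been selected with puromycin at 7 µg/ml and cloned, and the RNA of 5 clones was pooled for each arm. Each pool was hybridised to 1 Affymetrix array, which gave 1 array per group and 45101 probesets. The median signal was 15.4 on the empty-vector array and 14.1 on the miR-155 array, and the highest signals were 11141 and 11385. There was no replicate array, so no p-value was computed, and every difference below describes these 2 arrays only. The spread given beside a value is the robust SD of the log2 ratio among the 500 genes nearest in signal, or the 95% range of random gene lists. Neither measures the variation between clones or between cultures, which 1 array per group cannot separate from array noise.

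The manipulated microRNA itself was not measured by these probesets. Mir155hg, the host gene of miR-155, had 1 probeset, with a signal of 0.73 on the empty-vector array and 1.05 on the miR-155 array. Only 3.78% and 8.29% of the probesets of the respective arrays lay below it. This probeset checks nothing about the labels, because the part of the host transcript carried by the vector is not given in the sources used here.

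The stated purpose of the comparison was to find mRNAs that miR-155 regulates. Of 9097 genes in the upper 50% of mean signal, 175 were at least 2-fold higher and 130 at least 2-fold lower in the miR-155 array. At least 4-fold differences were found for 24 genes in the higher and 15 in the lower direction, and at least 1.5-fold differences for 484 and 545. Of the 2-fold genes, 56 and 51 had a reading below the signal floor of 25.8 on 1 array. No detection limit is known for such readings, so these genes are named below by their signals alone (empty vector first), with no ratio. With readings below the floor raised to it the counts were 153 and 109. No list median changed, which says little, since a list held at most 3 genes with such a reading. Large ratios were most frequent among dim genes: the dimmest 20% (median signal 43.5, robust SD of the log2 ratio 0.51) held 91 of the higher and 77 of the lower genes, and the brightest 20% (median signal 1107, robust SD 0.15) held 8 and 3. In simulated ratios with this spread, 133 of 8897 unchanged genes passed 2-fold. That spread was taken from the compared arrays themselves, with any real differences in it, so this is no measured count of false calls. The counts depended on the filter on dim genes, on an offset and on the use of several probesets: they were 36 and 11 in the upper 25% of signal, 62 and 26 with an offset of 50, 278 and 301 with the mean of all probesets, and 2072 and 2518 with no filter.

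The gene with the highest ratio was Fcgr2b, the inhibitory receptor for the Fc part of IgG, with a signal of 40.9 on the empty-vector array and 650 on the miR-155 array (15.9-fold, log2 ratio 3.99, local SD 0.27). Its 3 further probesets gave log2 ratios of 2.68 to 3.83. Ccnd2, encoding the G1 cyclin D2, read 31.0 and 445 (14.3-fold, log2 ratio 3.84, local SD 0.32), and its 3 further probesets were also higher, each with a reading below the floor on the empty-vector array. Tmem176a and Tmem176b, a pair of related membrane proteins, were 11.5-fold and 7.38-fold higher, and Tmem176b reached a signal of 2458. Gpnmb, a transmembrane glycoprotein of macrophages and osteoclasts, was 9.07-fold higher. Slpi, the secretory leukocyte protease inhibitor, read 73.5 on the empty-vector array and 469 on the miR-155 array. The 15 highest genes also included the regulator of G-protein signalling Rgs1 (2.57), the interferon-inducible Ifi202b (2.34), the annexin Anxa3 (2.33) and the transcription factor Egr1 (2.29). The other 5 had a reading below the floor: Tox2 (10.6 and 83.2), the ferroxidase ceruloplasmin (Cp, 11.9 and 78.1), the mitochondrial acetyl-CoA synthetase Acss1 (11.0 and 70.2), Rasal1 (16.3 and 101) and Tmem98 (19.5 and 108).

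At the other end, Hacd1, a dehydratase of very-long-chain fatty acid synthesis, read 481 on the empty-vector array and 45.1 on the miR-155 array (10.7-fold lower, log2 ratio −3.41, local SD 0.30), and its further probeset gave −2.55. Tcl1b3, of the Tcl1 family, read 935 and 137 (6.84-fold lower). The 15 lowest genes also included Dner, the biliverdin reductase Blvrb, Trp53i11, Fkbp11, Pgap4, Fam81a and Sgsm1, with log2 ratios from −2.41 for Dner to −2.01 for Sgsm1. The other 6 had a reading below the floor: Cnksr3 (80.4 and 11.0), Tctn2 (111 and 15.9), the cytochrome P450 Cyp2s1 (71.7 and 14.1), the mitochondrial adenylate kinase Ak4 (87.2 and 18.2, and 46.3 and 21.6 in its further probeset), Reep6 (106 and 22.9) and Atp6v0d2 (55.0 and 13.6). The 19 of these 30 genes with both readings at or above the floor lay at least 4.93 local SDs from the local median. They were picked for the size of their ratios, so this distance is no evidence for any of them. For 23 of the 30 no further probeset reached the signal floor, and the 2 further probesets of Sgsm1 disagreed with its ratio, at −0.19 and 0.38.

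**Figure D1:**
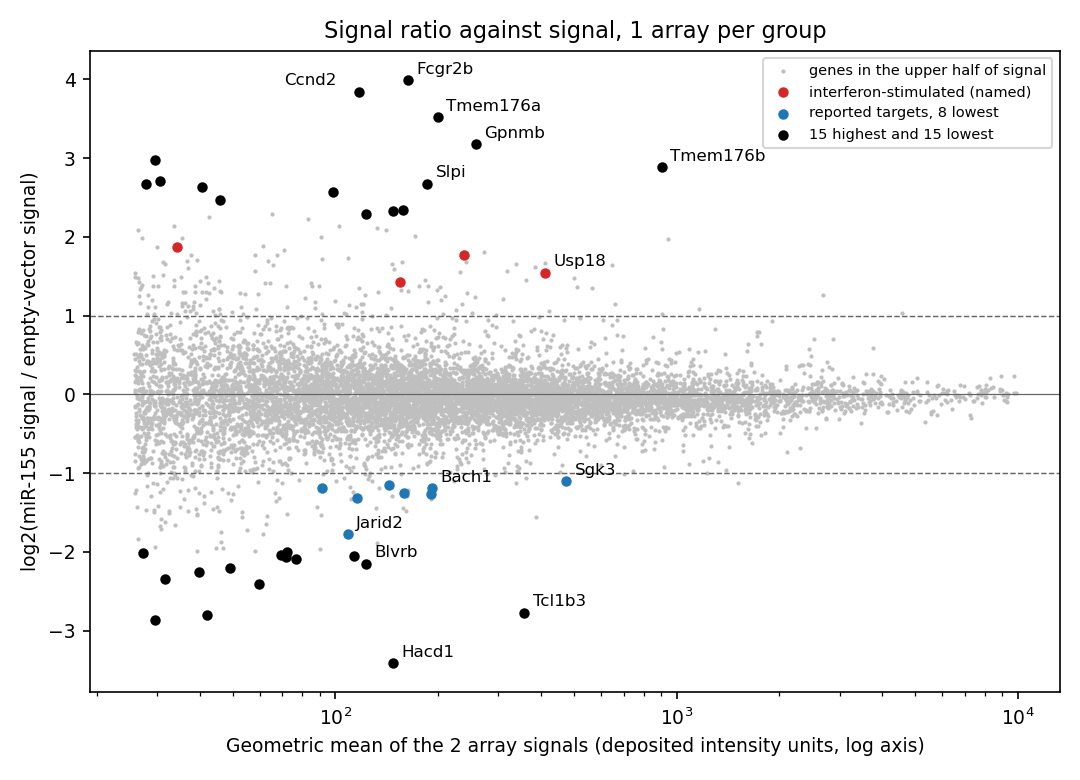
Log2 ratio of the miR-155 to the empty-vector signal (vertical axis) against the geometric mean of both signals (deposited intensity units, log axis) for the 9097 genes in the upper 50% of signal, 1 array per group. Dashed lines mark 2-fold, black points the 15 highest and 15 lowest genes, red points the 4 named interferon-stimulated genes and blue points the 8 lowest reported targets; the ratios widen towards dim genes, and Fcgr2b at 3.99 and Hacd1 at −3.41 lie at the ends.

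Genes that had been reported as miR-155 targets were shifted towards lower signal in the miR-155 array. Of 50 listed targets in the upper 50% of signal, 40 had a ratio below 0, 18 were at least 1.5-fold lower, 8 of these at least 2-fold lower, and 3 were at least 1.5-fold higher. The lowest were the chromatin regulator Jarid2 (201 against 58.9, 3.41-fold lower, log2 ratio −1.77, local SD 0.33), the tetraspanin Tspan14 (−1.32), the adaptor Sla (−1.27), the co-repressor Tle4 (−1.25), the repressor of heme oxygenase Bach1 (−1.19), the clock transcription factor Arntl (−1.19), Zfp652 (−1.15) and the kinase Sgk3 (−1.10). The 2 further probesets of Jarid2 read −1.65 and −2.28, that of Bach1 42.9 and 18.1 (signals), those of Sgk3 −0.84 and −0.67, but that of Tle4 only −0.36. Going the other way, Ets2 was 3.15-fold higher (log2 ratio 1.66), Pea15a 2.43-fold (1.28, against 0.42 in its further probeset) and Vav3 2.41-fold (1.27, against 0.64 and 0.81 in its further probesets). The list median was −0.38, below all 10000 random lists matched on signal, whose 95% range was −0.13 to 0.03. In the upper 25% of signal the median was −0.22, still below the 95% range of random lists drawn in that setting. Without the myeloid follow-up genes, which these arrays may have been used to choose, the median in the upper 50% of signal was −0.29.

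A shorter list held genes recalled from earlier work on miR-155 in myeloid cells, and all 9 measured members also belong to the reported targets. It is not independent evidence of a direction, since these arrays may have been used to choose its genes. All 9 read lower in the miR-155 array and 5 were at least 1.5-fold lower, with a median log2 ratio of −0.61 (random range −0.23 to 0.14). Besides Jarid2, Sla, Bach1 and Arntl, they were the myeloid transcription factors Spi1 (−0.61) and Cebpb (−0.53), Hif1a (−0.38), the receptor Csf1r (−0.25) and Cux1 (−0.08). The further probesets of Csf1r gave −0.99 and −0.96 and those of Cux1 −1.02 to −0.15, so the brightest probeset carried the smallest difference of each. The median was −0.38 in the upper 25% of signal.

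Interferon-stimulated genes formed the list with the highest median. All 29 members in the upper 50% of signal were higher in the miR-155 array, 25 of them at least 1.5-fold and 15 at least 2-fold. The antiviral Oasl2 read 18.0 and 65.7, and the log2 ratio was 1.76 for Trim30a (1.68 in its further probeset), 1.54 for the ISG15 protease Usp18 (signal 241 against 702, local SD 0.19) and 1.43 for the transcription factor Irf7. The median was 1.01, above all 10000 random lists (95% range −0.17 to 0.08). Of 15 genes of MHC class I presentation, 5 were at least 1.5-fold higher and none was as much lower, while 2, Calr (−0.20) and Canx (−0.0091), named after their values were seen, had a ratio below 0. The immunoproteasome subunits Psmb9 (1.15) and Psmb8 (0.73), the peptide transporter Tap1 (0.95) and the class I molecule H2-M3 (0.80) were the largest. That median was 0.44 (random range −0.16 to 0.06).

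**Figure D2:**
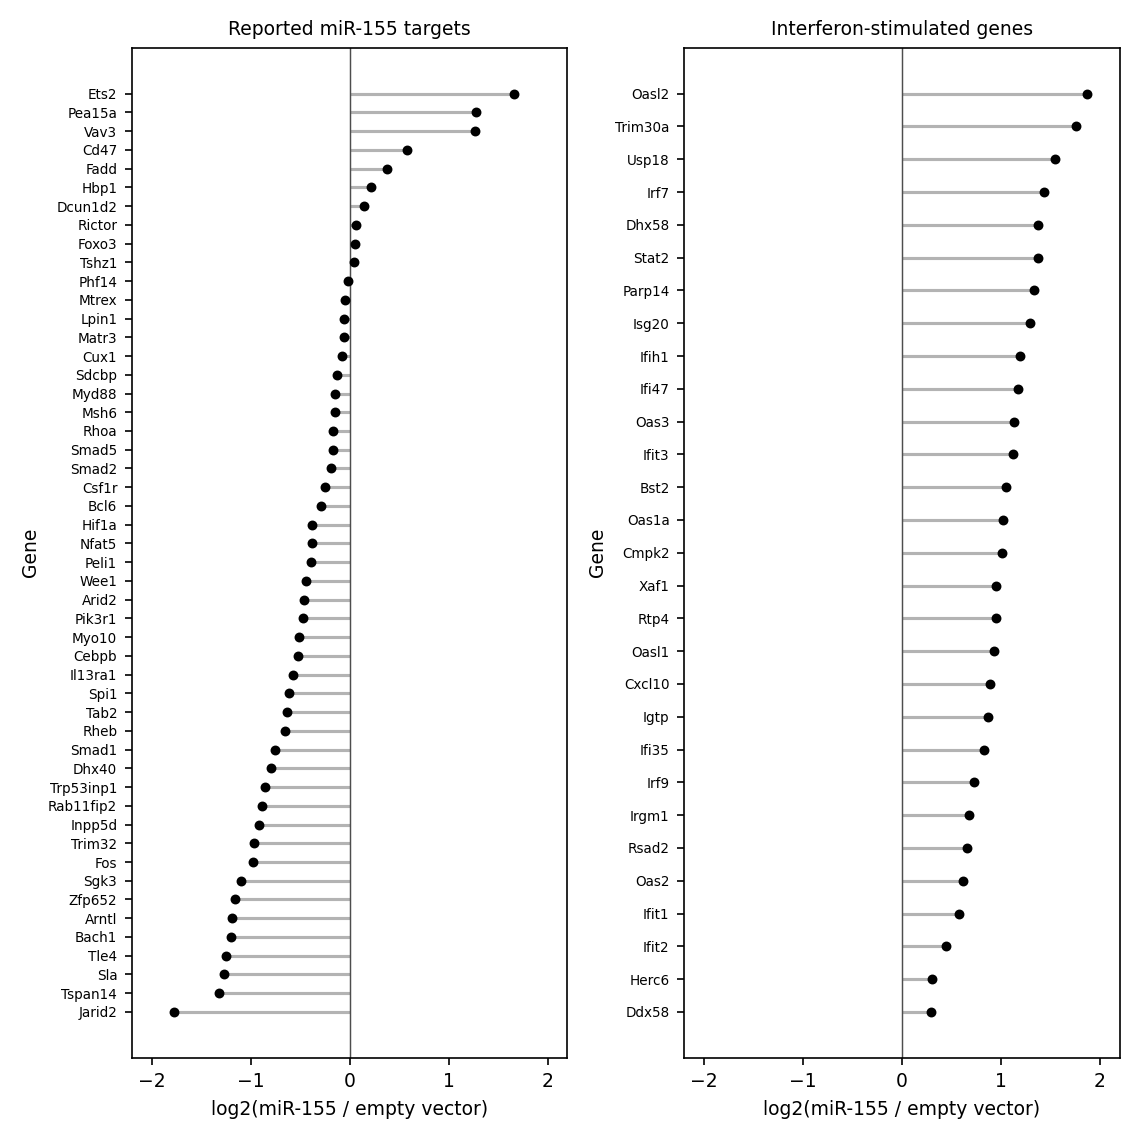
Log2 ratio of the miR-155 to the empty-vector signal (horizontal axis) of each gene in the upper 50% of signal (vertical axis), for 50 reported miR-155 targets (left) and 29 interferon-stimulated genes (right), 1 array per group. Of the targets, 40 lie below 0, down to −1.77 for Jarid2, and all 29 interferon-stimulated genes lie above 0, with Trim30a at 1.76; the highest point, Oasl2, rests on a reading below the signal floor.

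Inflammatory genes of the NF-κB response had an upward shift: 9 of 23 were at least 1.5-fold higher, none was as much lower, and 14 were within 1.5-fold, 5 of these with a ratio below 0. The median was 0.49 (random range −0.18 to 0.09), and 0.30 with an offset of 50. The largest ratios were those of the C-type lectin Clec4e (1.68), the prostaglandin synthase Ptgs2 (1.65), Cd40 (1.64) and Tnf (1.25). Of 11 chemokines and their receptors, 3 were at least 1.5-fold higher and 2 lower. Ccl3 was at 0.97, Ccl4 at 0.94, Cxcl10 at 0.89 and Cxcl1 at −1.43 (73.9 against 27.3, the latter just above the signal floor). Their median was 0.18 (random range −0.22 to 0.14), and 0.44 with no filter on dim genes, 0.34 with averaged probesets and 0.41 with plain probesets. Immediate-early genes went both ways, 7 of 22 at least 1.5-fold higher and 3 lower, with Egr1 at 2.29, the ERK phosphatase Dusp6 at 1.68 and Fosl2 at −1.96, and Egr3 read 19.5 and 93.1. The further probeset of Fosl2 read only −0.45. Their median of 0.30 lay above the random range (−0.19 to 0.12), but in the upper 25% of signal it was 0.17 and inside it, and with an offset of 50 it was 0.18.

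Genes of heme metabolism and the NRF2 response, which Bach1 represses in part, were shifted lower. Of 19 genes, 5 were at least 1.5-fold lower and 1 higher, and the median was −0.42 (random range −0.15 to 0.06). Blvrb read 259 against 58.4 (log2 ratio −2.15), the glutathione transferase Gstm1 −1.45 and Nfe2l2, which encodes NRF2, −1.01. Hmox1, heme oxygenase 1, was the 1 gene at least 1.5-fold higher, at 213 against 391 (0.88), and 6 of the 19 had a ratio above 0. The ratio of Nfe2l2 turned to 0.07 when all its probesets were averaged, but none of its further probesets reached the signal floor. The list median was −0.23 in the upper 25% of signal and −0.28 with averaged probesets.

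Cytoskeleton and adhesion genes had a small upward shift, with 5 of 37 at least 1.5-fold higher, 1 lower and a median of 0.11 (random range −0.11 to 0.02), which was 0.068 with averaged probesets, 0.18 with the median of all probesets set to 0 and 0.17 with quantile normalisation. Integrin Itgb7 read 0.94, the actin-binding Tmsb10 0.93 (0.49 to 1.30 in 3 further probesets) and Anxa1 0.79, against −0.97 for integrin Itga6 (−0.23 in its further probeset). With averaged probesets Anxa1 turned to −0.27, but none of its further probesets reached the signal floor. The median of 20 cholesterol synthesis genes was 0.10 (random range −0.16 to 0.06), but none reached 1.5-fold. Mvk (0.40, but −0.23 in its further probeset), Fdft1 (0.40), Pmvk (0.27) and Sqle (0.22) were the largest, and the median turned to −0.057 with averaged probesets and −0.036 with plain probesets, inside the range both times, and was 0.18 with the median of all probesets set to 0.

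The median of the macrophage genes lay inside its random range. Of 32, 7 were at least 1.5-fold higher and 4 lower, with a median of 0.025 (random range −0.12 to 0.03). Beside Fcgr2b and Gpnmb, the lipopolysaccharide co-receptor Cd14 was 2.40-fold higher (1728 against 4145), and Pilra read 21.5 and 48.5. The list left the random range upwards with no filter (0.13), with averaged probesets (0.059) and with plain probesets (0.18), and its median turned to −0.11 in the upper 25% of signal, inside the range there. Of 21 osteoclast genes, 6 were at least 1.5-fold lower and 2 higher. They included the vacuolar ATPase subunit Atp6v0d2 (55.0 and 13.6), Fosl2 (log2 ratio −1.96) and the transcription factor Nfatc1 (665 against 226, −1.56, with −1.10 to −0.62 in 4 further probesets), against 1.10 for Myo1d. Their median was −0.049 (random range −0.18 to 0.08), and −0.33 in the upper 25% of signal, below the range. Of 19 lipid efflux and storage genes, 4 were at least 1.5-fold higher and 2 lower. The scavenger receptor Cd36 (2240 against 1024, −1.13) and Pltp (−0.98) were lower, and Abca1 (0.87) and Scd1 (0.70) higher, around a median of −0.057.

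Lists of basic cell functions lay inside their random ranges. None of 30 ribosomal protein genes (median 0.018), 37 genes of mitochondrial respiration (−0.039), 31 of mitosis (−0.0051) or 13 housekeeping genes (−0.0014) differed by 1.5-fold, and of 32 genes of DNA replication (−0.10) 1 did, Mcm2 at −0.59, named after its value was seen. The medians were −0.075 for 23 genes of glycolysis and hypoxia, 0.016 for 30 lysosomal genes, −0.013 for 21 genes of microRNA processing and −0.020 for 30 of cytokine signalling. Among 30 genes of the endoplasmic reticulum and integrated stress responses (median −0.11), 3 were at least 1.5-fold higher, namely Ddit4 (0.85), Atf3 (0.81) and Trib3 (22.2 and 33.7, within 1.5-fold with the reading raised to the floor), while Atf5 read −0.50. Among 24 p53 and apoptosis genes (median −0.023), Casp4 (24.2 and 62.5) and Bcl2 (0.99) were higher and Trp53inp1 (−0.86) and Zmat3 (−0.83) lower. The stress list moved below its random range with averaged probesets (−0.17) and in the upper 25% of signal (−0.15). The lysosomal list moved above its range with averaged probesets (0.12), and the ribosomal list with averaged probesets (0.026) and with no filter (0.015).

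Markers of other cell types were mostly at the level of dim probesets. Of 19 B cell markers on the array 3 passed the signal filter, Blnk (0.57), Bank1 (0.55) and Ighm (−0.15). Their median of 0.55 lay above the random range (−0.36 to 0.28), and with no filter the list median was −0.68. Medians were inside the range for 5 dendritic cell markers (0.23, but 0.52 and above the range in the upper 25% of signal), 3 markers of fibroblasts and stroma (0.14) and 4 of erythroid cells and megakaryocytes (0.11). Only 2 MHC class II genes (Cd74 at 0.32 and H2-DMa at 0.30), 1 T or NK cell marker (Zap70 at −0.41) and 0 of 21 neutrophil and mast cell markers passed the filter, too few for a median. These 3 genes were named after their values were seen. Of 87 markers of B, T and NK, neutrophil and mast, stromal and erythroid cells, 14 reached the signal floor on the miR-155 array by their brightest probeset. By that probeset, 0 of these were at least 2-fold higher there. The 3 further probesets of Ighm went both ways: the highest read 18.6 and 54.2 (empty vector first), and the lowest had a log2 ratio of −0.42.

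**Figure D3:**
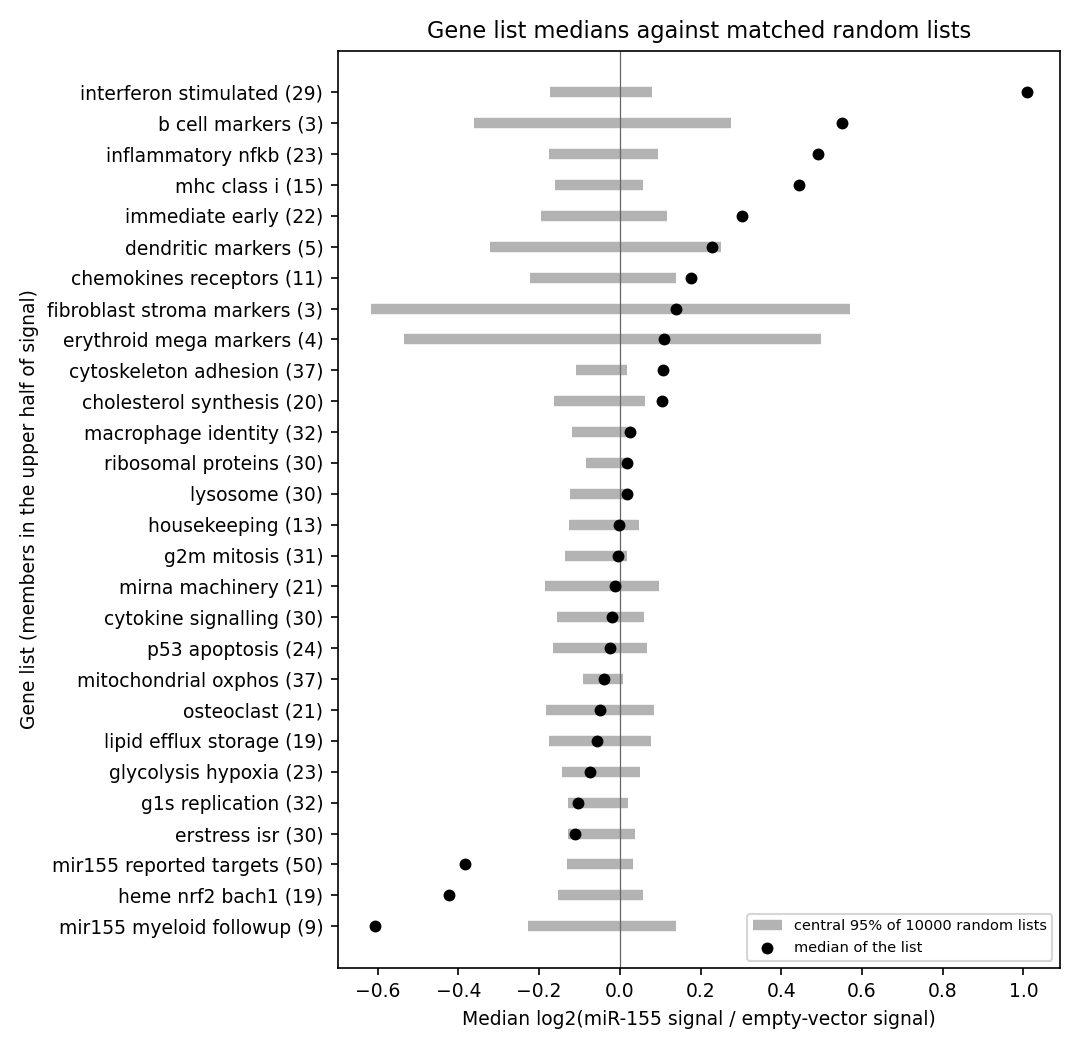
Median log2 ratio of the miR-155 to the empty-vector signal (points, horizontal axis) for 28 gene lists (vertical axis, members in the upper 50% of signal in parentheses), with the central 95% of 10000 random lists matched on signal (grey bars), 1 array per group. The interferon-stimulated list at 1.01 and the myeloid follow-up list at −0.61 lie at the ends, and 11 of the 28 medians lie outside their bar.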

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

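Both results here come from probesets left out of the gene counts, and no explanation was tested for either. Among the genes kept, 1.92% were at least 2-fold higher in the miR-155 array than in the empty-vector array and 1.43% at least 2-fold lower. Of 991 probesets above the signal floor with no listed gene, 14 (1.41%) were at least 2-fold higher and 28 (2.83%) at least 2-fold lower, so their higher share was not above that of the genes kept. The highest read 94.5 and 523 (log2 ratio 2.47). Of 505 probesets above the floor with several listed genes, 18 (3.56%) were at least 2-fold higher and 7 (1.39%) at least 2-fold lower. The highest of these read 28.3 and 218 (log2 ratio 2.95).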

How the results depend on the processing

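The target list without the follow-up genes and the raising of readings below the signal floor to it were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because there was 1 array per group, for which reason no array could be left out either. The alternatives on 3′ untranslated region sites were not run, as no transcripts were used here. The numbers of genes at least 2-fold higher and lower (175 and 130) became 2072 and 2518 with no filter, 36 and 11 in the upper 25% of signal, 62 and 26 with an offset of 50, and 278 and 301 with averaged probesets; of the main genes, the last setting shared 120 and 77. With readings raised to the floor they were 153 and 109, and no list median changed, though a list held at most 3 genes with such a reading. The share of higher genes among these calls was 57.4%, and 62.3% to 65.3% under the 3 other scalings, 76.6% in the upper 25% of signal, 70.5% with an offset of 50 and 51.5% with plain probesets. Lower genes were the majority with no filter and with averaged probesets, where the share was 45.1% and 48.0%. The medians of targets, follow-up, interferon, inflammatory, chemokine, MHC class I, heme and cytoskeleton genes stayed on their side of the random range under all 8 alternatives chosen before, and the target median was −0.29 without the follow-up genes. Moved here means by more than the SD of the matched random lists, a measure chosen after the data were seen. With the median log2 ratio set to 0, the medians that moved were targets −0.31, interferon 1.09, inflammatory 0.57, macrophage 0.10, osteoclast 0.029, MHC class I 0.52, lysosome 0.094, cholesterol 0.18, lipid 0.021, glycolysis 0.0027, heme −0.35, stress −0.035, replication −0.026, mitosis 0.073, p53 0.054, ribosomal 0.10, respiration 0.039, housekeeping 0.076, microRNA processing 0.064, cytoskeleton 0.18 and cytokine signalling 0.057. With quantile normalisation, the medians that moved were targets −0.34, MHC class I 0.50, lysosome 0.059, lipid 0.025, replication −0.065, respiration 0.0089 and cytoskeleton 0.17. With loess, the medians that moved were targets −0.33, macrophage 0.071, lysosome 0.065, lipid 0.032, glycolysis −0.019, heme −0.37, stress −0.057, replication −0.055, mitosis 0.049, ribosomal 0.050, respiration 0.0036, housekeeping 0.049, cytoskeleton 0.15 and cytokine signalling 0.043. With no filter, the medians that moved were chemokines 0.44, macrophage 0.13, B cell −0.68, dendritic −0.16 and erythroid −0.44. In the upper 25% of signal, the medians that moved were targets −0.22, follow-up genes −0.38, macrophage −0.11, osteoclast −0.33, heme −0.23, immediate-early 0.17, dendritic 0.52 and cytokine signalling −0.12. With an offset of 50, the medians that moved were targets −0.32, interferon 0.74, inflammatory 0.30, MHC class I 0.36, heme −0.36 and immediate-early 0.18. With averaged probesets, the medians that moved were targets −0.46, interferon 0.88, inflammatory 0.38, chemokines 0.34, MHC class I 0.53, lysosome 0.12, cholesterol −0.057, heme −0.28, stress −0.17, immediate-early 0.22, dendritic 0.060, cytoskeleton 0.068 and cytokine signalling −0.17. With plain probesets, the medians that moved were targets −0.45, inflammatory 0.38, chemokines 0.41, macrophage 0.18, cholesterol −0.036, mitosis −0.056, p53 −0.090, respiration −0.094 and stromal −0.22. Beyond those, 2 named genes turned with averaged probesets, Nfe2l2 to 0.071 and Anxa1 to −0.27. No further probeset of either gene reached the signal floor, so both turns came from averaging in probesets below it. For the 95 named genes, 584 of 663 alternative values moved by less than the local SD and 77 by more with the direction kept or the gene within 1.5-fold. Many of the values could not move. The filters leave the ratio of a gene that passes as it was, and averaging does so for a gene with 1 probeset. The 0.078 added by setting the median to 0 is below the local SD of every named gene (lowest 0.11, Csf1r). Fewer or more genes are counted with another filter by construction. Setting the median to 0 adds 0.078 to every log2 ratio, so that those medians shift by construction and keep their percentiles. For the other changes, those under quantile normalisation and loess included, the cause was not tested. Dim genes limit the counts, since the robust SD of the ratio was 0.51 in the dimmest 20% of genes and 0.15 in the brightest 20%.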

Other observations

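The gene family scan, the shuffle of adjacent genes, and the tests of RNA from another cell type, of targets picked from these arrays, of faulty probesets and of vector insertion were chosen after the results were seen; the other tests were planned before their values were seen. Grouping the genes kept by the letters that open their symbol gave 135 families of at least 8 genes, of which 4 lay below and 5 above the 95% range of 2000 random lists each, against 6.75 expected outside it by chance, so single families weigh little. The highest was the interferon-inducible Ifi family (9 genes, median log2 ratio 1.17, 6 at least 1.5-fold higher), which overlaps the interferon list, with Ifi27l2a at 1.97 (476 against 1861) and Ifi44l at 1.66. The Parp family had a median of 0.45 (9 genes, 3 at least 1.5-fold higher). Annexins, which bind membrane phospholipids with calcium, had a median of 0.38 (8 genes): Anxa3 (2.33), Anxa4 (0.83), Anxa1 (0.79), Anxa2 (0.39), Anxa7 (0.37) and Anxa5 (0.14) read higher and Anxa6 (−0.60) and Anxa9 (−0.60) lower. Krüppel-like transcription factors had a median of −0.37 (10 genes, 2 at least 1.5-fold lower), with Klf4 at 441 against 276 (−0.67) and Klf9 at 324 against 202 (−0.69). The medians of the Ifi, Parp, annexin and Klf families kept their sign under the 3 other scalings, where that of Klf ran from −0.32 to −0.30. All genes in this paragraph except Anxa1 and Anxa3 were named after their values were seen.

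Members of the immune lists below the signal filter went both ways. In the miR-155 array 6 of 7 such interferon-stimulated genes, 10 of 17 inflammatory genes and 13 of 18 chemokines and receptors read higher, and 1, 7 and 5 lower. Acod1 (0.74 against 45.2, empty vector first), Ifi204 (0.68 against 26.2), Irak3 (9.68 against 60.5) and Zbp1 (7.98 against 46.4) read higher, and Ccl2 (24.0 against 7.61), Cxcr4 (12.3 against 4.18) and Iigp1 (21.8 against 17.1) lower. These genes were chosen after their values were seen, and only signals are given, as for every gene with a reading below the floor.

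Interferon-stimulated genes were higher in the miR-155 array, with a median log2 ratio of 1.01 over 29 genes. Scaling between the arrays could not be decided by the other scalings (lowest median 1.05). They moved the median of all genes by at most 0.078. A common scaling would move random lists of like signal too, and the list median lay above all 10000 of them. This argued against a common scaling. Probesets shared between family members were argued against by a median of 0.95 over plain probesets. RNA from T and NK, neutrophil and mast, stromal or erythroid cells was argued against. By the brightest probeset, 0 of 87 markers of these and B cells reached the floor on the miR-155 array and were 2-fold higher. For B cells it stays open, as the values went both ways. A further probeset of Ighm read 18.6 and 54.2 (empty vector first), and the B cell list median of 0.55 over 3 genes lay above its random range. With no filter that median was −0.68, and of 16 B cell markers below the filter 10 read lower and 6 higher. Dendritic cell markers were not part of this test. A difference between clones or cultures, such as an interferon response in 1 pool, cannot be told apart from an effect of miR-155, because there was 1 array per group. Whether miR-155 may raise these genes therefore stays a hypothesis, and independent pools would bear on it.

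Reported miR-155 targets were lower in the miR-155 array, with a median of −0.38 over 50 genes. Whether targets had been picked from these arrays was not decided. The list without the 9 follow-up genes still had a percentile of 0, so those genes alone do not account for the shift. Other listed targets could have been chosen on these or similar arrays. The other scalings (highest median −0.31) could not decide on scaling between the arrays, since they moved the median of all genes by at most 0.078. A common scaling was argued against by random lists of like signal, which it would move too: the list median lay below all 10000. Noise of dim probesets was argued against by −0.22 in the upper 25% of signal. Repression by the vector's microRNA is consistent with these values as a hypothesis, but differences between the clone pools stay open here too, and the seed-site analysis that would bear on it was not run. Ets2, Pea15a and Vav3 went against it.

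The 30 genes with the largest differences were checked in further probesets. Over the 7 genes that have one, the median of the further probesets, signed by the gene, was 2.79 (2.55 with readings below the floor raised to it). A single faulty probeset was argued against for 6 of the 7, whose further probesets had the same direction. For Sgsm1, whose further probesets disagreed with its ratio, it stays open. For the 23 with no further probeset it cannot be told apart from a true difference. Vector insertion acting on neighbouring genes was not decided. The 26 neighbours of the 15 highest genes had a median log2 ratio of 0.11, at percentile 99.78 of random lists. For the neighbours of the other 160 genes at least 2-fold higher the percentile was 53.53. That contrast is partly built in: only the 15 genes themselves were removed from the first set, which kept Myo1d (1.10) and Mndal, both at least 2-fold higher. Every gene at least 2-fold higher was removed from the second set. The neighbours of the 15 lowest genes were not examined. The comparison with the other genes and the removal of family members were added to this test one after the other, once a first percentile had been seen. Family members were taken by the letters that open the symbol, with Mndal added by hand. Without them the percentile was 97.9, just above the upper end of the 95% range, so the test is a weak hint at most. Tmem176b, Tmem176a and Gpnmb are adjacent among the genes kept, and 11 adjacent pairs were both at least 2-fold higher, against a median of 3 and a maximum of 10 in 1000 shuffles, which shared regulation of neighbouring genes would give as well.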
